A study of Mus musculus with 3 samples.

How the data were processed

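The data were RNA sequencing libraries of total RNA from mouse microglia, 3 replicates of 1 group, with the genotype and the inhibitor taken from the sample labels. Per the labels' protocols, RNA was extracted with a Direct-zol column kit and its amount and integrity were checked on a Bioanalyzer. The name, dose and exposure time of the inhibitor, whether it was given to mice or to isolated cells, and the library preparation and strandedness were not given in the sources used here. Strand being unstated, reads of overlapping and antisense genes could not be told apart. The series design text describes microglia with and without Mir137 and gives 4 mice, without saying which animals went into which replicate.

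The authors deposited a table of estimated counts per gene and a table of FPKM per gene, each with 1 column per replicate. Per the submitters' processing notes, STAR 2.7.9a, RSEM and DESeq2 were used with the GRCm38 and mm10 builds. Their settings and the gene annotation were not given in the sources used here. The deposited estimated counts were not normalised between libraries, and 4.07% of the values were not whole, as when RSEM divides a read between genes it could come from. Such division makes the values of near-identical genes, such as the globin genes, uncertain. The deposited FPKM values divide the counts by library size and by the effective length of the gene, which is its length reduced by what a fragment occupies. FPKM of genes with effective lengths near the fragment size are therefore very sensitive to that estimate. The effective length was recovered from the ratio of a gene's count to its FPKM and the library total.

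The tables listed the same 24411 genes apart from 12 gene names that a spreadsheet had turned into dates. These were written as serial numbers in 1 table and as day and month in the other, were joined by date, and were not named or assigned to a list. There were 0 columns of other samples. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38, in which 23323 of the symbols matched exactly 1 gene. Coordinates are 1-based.

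The 33 gene lists with 443 symbols, the rule for named genes, the tests and the alternatives were fixed before the data were examined. Of these symbols 428 were found, 1 of them under an older name (Vsir as 4632428N05Rik). Ly6g, Trac and the mitochondrially encoded genes were not matched, which left 32 lists. The genes named always were Spi1, Mir137, Tmem119, Jdp2, Csf1r, Cx3cr1, P2ry12, Sall1, Trem2 and Apoe. The rule added the 10 genes highest in mean FPKM, the 3 highest and the 1 lowest member of each list by mean FPKM, and the 10 genes with the highest tagwise dispersion among those with a mean of at least 10 CPM. Some genes that the rule names are not reported here. Ratios between pairs of genes, and the removal of the length trend, were chosen after the values were seen. Another 10 lists, used in the closing observations, were written later but before their values were seen. The further lists hold Toll-like receptors, purinergic and adenosine receptors, chemokine and cytokine receptors, lipid and cholesterol, glycolysis, iron handling, and additional neutrophil, choroid plexus, endothelial and neuronal genes.

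A gene was called detected at an FPKM of at least 1 in all 3 libraries. The level of a list in a library was the median over its measured members of log2(FPKM + 1), with a pseudocount of 1. The median was also ranked among those of 10000 random lists of the same size drawn from all genes. Differences between the homeostatic list and another list were taken within each library and tested by an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25.

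For the spread between libraries, estimated counts were rounded to whole numbers. Genes were kept by the default filter of edgeR 4.0.16 (R 4.3.3), which left 13246, and TMM normalization and common and tagwise dispersions were computed with an intercept alone. The square root of a dispersion is the biological coefficient of variation. A chi-square test of homogeneity of the 3 counts given the effective library sizes, with Benjamini-Hochberg adjustment at 0.05, compared libraries and not conditions. It was tested on simulated counts for the 13246 genes with 200 genes changed in 1 library. With counting error alone it recovered 83.5, 90.5 and 100% of changes of 1.5, 2 and 4 times, and called at most 0.0693% of unchanged genes. With a simulated coefficient of 0.1 the edgeR estimate was 0.104, 0.112 and 0.147 for those 3 sizes of change, and the chi-square test called 47.6 to 47.8% of unchanged genes. It therefore responds to spread that all genes share as well as to changes of single genes. For each of 30 lists with at least 5 members tested, the SD over the libraries of the mean log2(CPM + 1) was ranked among 10000 random lists matched on mean expression in 20 bins. A simulated change of 2 times in the neuronal, endothelial or monocyte list placed that list at percentile 100. In these simulations 1, 2 and 0 unchanged lists, in the same order, were also at or above percentile 95. Changes as small as those found between the libraries were not simulated.

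The alternatives were other detection limits (0.1 or 5 FPKM, 10 counts, any library), pseudocounts of 0.1 and 0.01, TPM and TMM CPM in place of FPKM, means over members, and leaving out members under 0.1 FPKM. For the spread they were size factors and dispersion from DESeq2 1.42.0, total counts, no filter, a mean count of at least 100, leaving out ribosomal protein genes, 50 bins, and leaving out each replicate in turn. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The depth of 15710750 to 17180404 counts per library puts the limit for a count of 0 at 0.175 to 0.191 CPM, taken as 3 counts. No comparison with untreated or wild-type microglia was made, because those libraries were not analysed here.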

Results

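RNA sequencing measured gene expression in microglia, the resident macrophages of the brain, from adult C57BL/6J mice carrying a deletion of Mir137. The libraries were labelled as treated with a Pu.1 inhibitor, and whether it was given to the mice or to isolated cells was not given in the sources used here. Mir137 encodes the microRNA miR-137, and Pu.1, encoded by Spi1, is the transcription factor on which macrophage and microglial identity depends. The deletion relied on a Cre recombinase that tamoxifen activates and that is expressed from Tmem119, a gene used as a microglial marker. The labels gave the age as 6 to 8 weeks and the tissue as brain, and the series design placed tamoxifen injection on 7 days in a row at 7 to 8 weeks of age. The 3 libraries formed 1 group, replicates 1 to 3. Knockout microglia without the inhibitor and microglia with intact Mir137 were not analysed here, so the values describe levels under the combined condition, and no effect of the deletion or of the inhibitor was estimated. The labels did not say that the replicates came from separate animals, so p-values measured only the spread between these samples, which may be technical.

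The libraries held 17180404, 15710750 and 16356125 estimated counts for replicates 1, 2 and 3, a mean of 16415760 ± 736640 (SD, n = 3). Of the 24411 genes tabulated, 14946 had a count in all 3 libraries, 11680 reached an FPKM of at least 1 in all 3, and 7430 had no count in any. A library contained 15912 ± 45.2 genes with a count (SD, n = 3). The 10 most abundant genes took 6.63 ± 0.12% of the counts (SD, n = 3). A gene with 0 counts could still have been present at up to 0.175, 0.191 and 0.183 CPM (counts scaled to library size) in replicates 1, 2 and 3, limits that correspond to 3 counts and cover counting error only.

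The most abundant transcripts were those of lysosomal and secreted proteins of macrophages. Cst3, a secreted inhibitor of cysteine proteases, had the highest level, 16246 ± 1196 FPKM (mean ± SD, n = 3, as for all FPKM values given in this form). Ctsd, a lysosomal aspartic protease, reached 5935 ± 232 FPKM. Also among the 10 highest were S100a8 at 8800.0 ± 567, Tmsb4x at 7246 ± 586, Ttr at 5690.0 ± 404, Eef1a1 at 4082 ± 165, S100a9 at 4056 ± 210, B2m at 3929 ± 150 and Rps27rt at 3893 ± 222 FPKM. S100a8 and S100a9 are calcium-binding proteins abundant in neutrophils, and Ttr encodes the transthyretin secreted by the choroid plexus. The ranking depended on the unit for short transcripts: S100a8, with an effective length of 113 nt, was at rank 2 in FPKM and at rank 90 in CPM, and Rps27rt, with 69.7 nt, at rank 10 and 601. In CPM, Ctsd was at rank 2 and Csf1r at rank 3.

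The targeted gene was examined first. Mir137 (GRCm38 chromosome 3, 118433857 to 118433929, a microRNA gene) had 0 counts in each of the 3 libraries. That 0 carried no information on the deletion, because none of the 1163 microRNA loci in the table had a count (0 of 1163), while all 6 microRNA host genes had counts, as did 1 of 110 small nucleolar RNA loci. Tmem119 (chromosome 5, 113793729 to 113800516), from which the recombinase was expressed, was at 167 ± 10.1 FPKM, with 172, 173 and 155 FPKM in replicates 1, 2 and 3.

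The next question was how strongly genes of microglia and of other cell types were expressed in the same libraries. All 27 measured homeostatic microglial genes were detected at an FPKM of at least 1 in every library, and 26 of them had a mean of at least 100 FPKM. Csf1r, the receptor for CSF1 on which microglial survival depends (chromosome 18, 61100598 to 61132149), was at 2370.2 ± 54.3 FPKM. P2ry12, a purinergic receptor of surveying microglia (chromosome 3, 59216272 to 59262871), was at 1608 ± 7.79, and Cx3cr1, the fractalkine receptor (chromosome 9, 119901616 to 120069879), at 1082 ± 10.3 FPKM. Trem2, a lipid-sensing receptor (chromosome 17, 48346401 to 48354147), was at 697 ± 54.7 and Sall1, a transcription factor of microglial identity (chromosome 8, 89027235 to 89044162), at 134 ± 5.88 FPKM. Lgmn, a lysosomal protease, reached 2668 ± 95.8 FPKM, and the lowest member, the fructose transporter gene Slc2a5, was at 93.4 ± 0.10 FPKM.

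Together the homeostatic genes took 6.02 ± 0.11% of all counts (SD, n = 3). The median of log2(FPKM + 1) over their members, used as the level of a list, was 9.04 ± 0.02 (SD, n = 3). The 14 genes shared by macrophages in general, all detected, had a level of 8.53 ± 0.04, with Ctss at 3833 ± 139, Laptm5 at 1087 ± 32.4, Tyrobp at 962 ± 87.0 and the lowest, Cybb, at 33.2 ± 1.79 FPKM. That level was 0.51 ± 0.04 log2 units below the homeostatic level within the same library (SD of the difference, n = 3). With TMM-normalised CPM in place of FPKM the homeostatic and general macrophage levels were 10.04 and 9.09.

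Among genes of other cell types, those of neutrophils and endothelial cells came closest to the homeostatic level. All 11 neutrophil genes were detected, at a level of 7.05 ± 0.10, which was 1.99 ± 0.11 log2 units below the homeostatic level. Besides S100a8 and S100a9, the granule protein gene Ngp was at 592 ± 5.75 FPKM and the lowest, myeloperoxidase (Mpo), at 11.7 ± 1.47 FPKM. All 12 endothelial genes were detected, at a level of 6.60 ± 0.09 and 2.44 ± 0.11 below the homeostatic level. Ly6c1 was at 1038 ± 66.6, the glucose transporter Slc2a1 at 486 ± 8.91, Itm2a at 356 ± 20.3 and VE-cadherin (Cdh5) at 30.2 ± 1.87 FPKM. Ly6c1 had estimated counts of 9627.78, 9818.93 and 9321.28, which were not whole, so its reads may be split with a related gene. The order of these lists depended on the unit: with TMM-normalised CPM in place of FPKM the homeostatic level exceeded the neutrophil level by 2.88 and the endothelial level by 1.60 log2 units.

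Genes of blood monocytes and of the macrophages that line brain borders were detected at intermediate levels. The 9 monocyte genes had a level of 5.08 ± 0.14, 3.96 ± 0.14 below the homeostatic level, with Chil3 at 335 ± 13.3, Ly6c2 at 130 ± 21.4, Plac8 at 121 ± 10.7 and Itga4 at 5.08 ± 0.36 FPKM. Ly6c2 also had estimated counts that were not whole, 1100.22, 1259.07 and 969.72, so its value is uncertain in the same way as that of Ly6c1. The 11 genes of border-associated macrophages had a level of 4.52 ± 0.23, 4.52 ± 0.22 below, with Stab1 at 82.3 ± 2.95, Pf4 at 68.6 ± 6.61, the mannose receptor Mrc1 at 61.3 ± 3.40 and Siglec1 at 5.97 ± 0.61 FPKM. P2ry12 exceeded Mrc1 by 26.3 ± 1.46 times and Cx3cr1 exceeded the monocyte receptor Ccr2 by 80.5 ± 1.49 times in FPKM (SD, n = 3). All 9 genes of ependymal cells and choroid plexus were detected, at a level of 5.0 ± 0.08 and 4.05 ± 0.08 below the homeostatic level. After Ttr, Enpp2, the gene of the secreted enzyme autotaxin, reached 850.0 ± 43.2 and the folate receptor Folr1 42.8 ± 5.26 FPKM, and the ciliary regulator Foxj1 was lowest at 1.93 ± 0.43 FPKM. These 9 genes took 0.83 ± 0.05% of counts, above the shares of the endothelial genes (0.47 ± 0.01%) and the neutrophil genes (0.37 ± 0.01%). That share rested on Ttr and Enpp2, which took 0.81 ± 0.05% of counts, while the other 7 genes took 0.024 ± 0.00079%.

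Glial and mural genes were lower. The 14 astrocyte genes, all detected, had a level of 3.73 ± 0.18, 5.31 ± 0.18 below the homeostatic level, with Clu at 168 ± 14.2, the glutamate transporter Slc1a3 at 101 ± 1.72, Atp1b2 at 34.0 ± 1.29 and Aldh1l1 at 2.73 ± 0.30 FPKM. The 12 oligodendrocyte genes, all detected, had a level of 3.68 ± 0.24, 5.36 ± 0.23 below, including the myelin genes Mal at 86.7 ± 2.78 and Cnp at 41.2 ± 4.44, with Myrf at 1.26 ± 0.17 FPKM. Of 12 mural and fibroblast genes 9 were detected, at a level of 3.09 ± 0.28, 5.95 ± 0.28 below, with the pericyte gene Rgs5 at 118 ± 15.7, Acta2 at 63.5 ± 3.24, Vtn at 59.0 ± 2.33 and Lum at 0.30 ± 0.08 FPKM.

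Neuronal, lymphocyte and oligodendrocyte precursor genes were near or under the detection limit. Only 3 of 16 neuronal genes were detected, Stmn2 at 14.2 ± 0.92, Tubb3 at 2.80 ± 0.75 and Map2 at 2.47 ± 0.21 FPKM, and the neurofilament gene Nefl had no count. The neuronal level was 0.49 ± 0.13, 8.55 ± 0.14 below the homeostatic level. Of 14 lymphocyte genes 5 were detected (level 0.76 ± 0.08, 8.28 ± 0.07 below), including Cd79b at 16.4 ± 2.96, Gzma at 10.2 ± 3.07 and Nkg7 at 3.89 ± 0.89, whereas Cd8a was at 0.07 ± 0.09 FPKM. Of 9 precursor genes 4 were detected (level 0.81 ± 0.22, 8.23 ± 0.22 below), including Olig1 at 5.48 ± 1.34, Vcan at 2.57 ± 0.32 and Cspg4 at 2.21 ± 0.32 FPKM, and Neu4 had no count. The pseudocount of 1 limits these differences. With pseudocounts of 0.1 and 0.01 they were 10.08 and 10.39 for neuronal, 9.39 and 9.57 for lymphocyte, and 9.30 and 9.47 log2 units for precursor genes.

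Of 7 erythroid genes 3 were detected, at a level of 2.03 ± 1.76, 7.02 ± 1.77 below the homeostatic level. That level rested on replicate 3, with 0.84, 1.19 and 4.05 in replicates 1, 2 and 3, and without replicate 3 it was 1.01 and the difference 8.03. Erythroid transcripts were not higher in replicate 3: their share of counts was 0.0084, 0.0095 and 0.0073% in replicates 1, 2 and 3. The median fell on Alas2 in replicates 1 and 2 (0.79 and 1.28 FPKM). In replicate 3, where Hba-a1 was given counts, it fell on Hbb-bt (15.57 FPKM). Hba-a2 was at 199.5 ± 66.5, Hbb-bs at 49.8 ± 19.4, Hbb-bt at 16.1 ± 0.47 and Slc4a1 at 0.02 ± 0.02 FPKM. The alpha globin values are uncertain because reads can be split between near-identical copies: Hba-a1 had 0, 0 and 136 estimated counts and Hba-a2 903, 1197 and 651 in replicates 1, 2 and 3, which summed to 903, 1197 and 787. Beta globin genes share sequence in the same way.

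The homeostatic level exceeded that of each of the 12 lists of other cell types and that of the general macrophage list in 3 of 3 libraries. Pooled over the 12 lists, 102 of 136 genes were detected, and the homeostatic median lay 5.51 ± 0.15 log2 units above the pooled median (SD, n = 3). An exact two-sided sign-flip permutation test of each difference gave p = 0.25, the smallest that 3 libraries allow, so none could pass a threshold of 0.05.

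**Figure D1:**
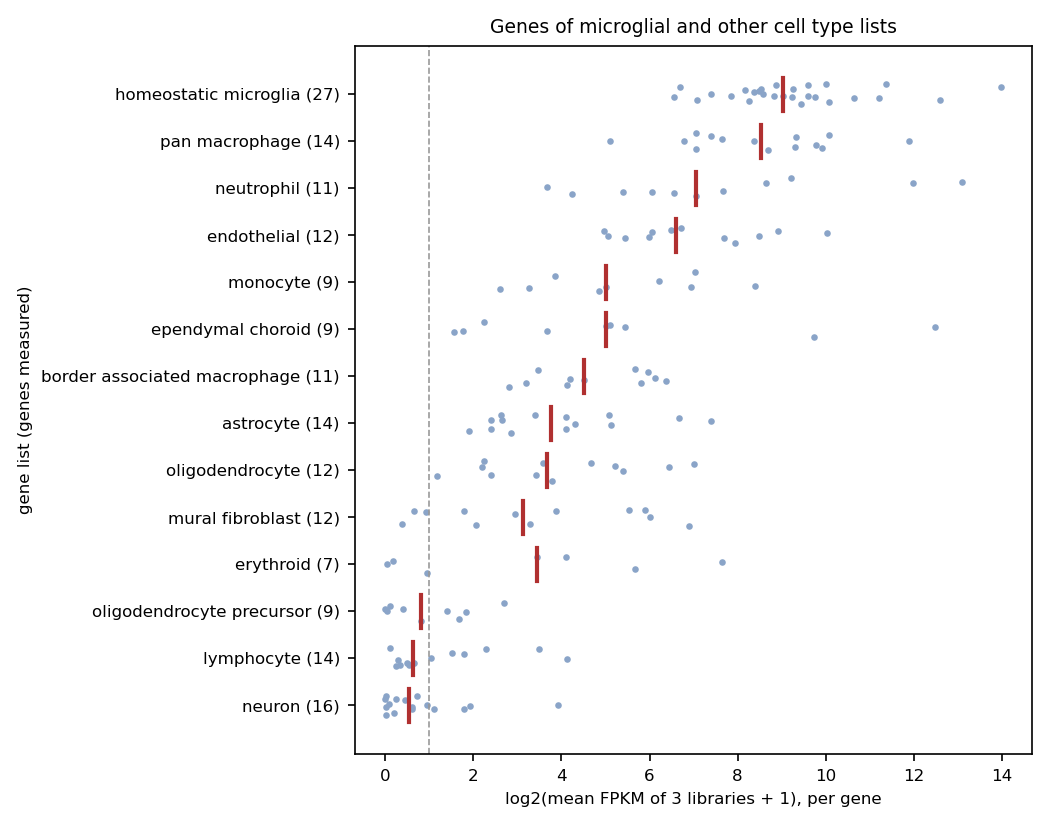
Each point is 1 gene at its mean over the 3 libraries on the axis of log2(FPKM + 1), with the number of genes measured in each list in brackets, the red bar at the list median and the dashed line at an FPKM of 1. Homeostatic genes all lie above 93 FPKM, all neutrophil and endothelial genes lie right of the dashed line, and 15 of 16 neuronal genes are under 10 FPKM.

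The transcription factor that the inhibitor targets was expressed, together with most of its partners and reported target genes. Spi1 (chromosome 2, 91082390 to 91115756) was at 187 ± 4.65 FPKM, with 187, 191 and 182 FPKM in replicates 1, 2 and 3. Of the 17 transcription factors that include Spi1, its ETS relatives and its partners, 15 were detected, at a level of 5.55 ± 0.08. Cebpa was the highest at 338 ± 3.52 FPKM, 0.552 ± 0.013 being the ratio of Spi1 to Cebpa, and Mef2a was at 183 ± 12.4 FPKM. Spi1 stood at 1.53 ± 0.06 times the partner Irf8. The close Spi1 relative Spib was at 0.14 ± 0.14 FPKM.

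All 27 reported Pu.1 target genes were detected, at a level of 7.04 ± 0.06 and with 2.07 ± 0.02% of counts, and 17 of them had a mean of at least 100 FPKM. After Csf1r and Laptm5 the highest was the Fc receptor gene Fcgr3 at 977 ± 42.7 FPKM, and the lowest was Csf2ra at 29.4 ± 1.5 FPKM. Of these 27 genes, 10 also belonged to another list, so this level was not independent of the homeostatic and macrophage levels.

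Genes of AP-1 and related basic leucine zipper transcription factors, several of which are induced within minutes of stimulation, were abundant. Of 15 measured, 14 were detected, at a level of 6.74 ± 0.09. Fos was at 2083 ± 31.9, Jun at 1498 ± 38.8 and Junb at 930.3 ± 25.9 FPKM, and Fosl1 was lowest at 0.07 ± 0.12 FPKM. Jdp2, which encodes a dimerization partner and repressor of Jun (chromosome 12, 85599027 to 85639878), was at 21.2 ± 1.71 FPKM, a ratio to Jun of 0.0141 ± 0.0012. Of the 15 AP-1 genes, 5 also belonged to the list of genes induced by tissue dissociation.

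Of 12 reported miR-137 targets, 8 were detected, at a level of 3.29 ± 0.10. The small GTPase gene Cdc42 was at 425 ± 12.1, Tcf4 at 23.9 ± 1.68 and the histone demethylase gene Kdm1a at 23.4 ± 1.46 FPKM. Zfp804a had no count. The medians of the partner, target and AP-1 lists were above all 10000 random lists of equal size (percentile 100), and that of the miR-137 targets was at percentile 93.96. A high percentile was easily reached, because random lists had medians near 1 and 7430 genes had no count.

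Genes of activation and effector functions were mostly detected, 162 of 170 over the activation lists. Lysosomal genes were the most abundant group: all 21 were detected at a level of 8.82 ± 0.02 with 4.62 ± 0.13% of counts, and the lowest, the transcription factor Tfeb, was at 17.4 ± 1.47 FPKM. All 14 complement genes were detected, at a level of 5.87 ± 0.05. The subunits of the initiating component C1q were among the highest transcripts, with C1qb at 2997 ± 202, C1qc at 2252 ± 106 and C1qa at 1751 ± 216 FPKM, whereas Cfb of the alternative pathway was at 3.0 ± 0.55 FPKM. Of 18 phagocytosis genes 17 were detected, at a level of 5.90 ± 0.02, with Cd68 at 639 ± 12.4 and Megf10 at 0.84 ± 0.17 FPKM.

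All 20 genes of disease-associated microglia were detected, at a level of 5.0 ± 0.12, but their levels were widely spread. Apoe, which encodes a lipid carrier (chromosome 7, 19696109 to 19699188), was at 814 ± 121 FPKM and the cathepsin Ctsb at 725 ± 13.1 FPKM. At the other end, 5 members were under 10 FPKM, and these were Cst7 at 8.63 ± 1.69, Lpl at 7.99 ± 0.51, Itgax at 5.29 ± 0.42, Gpnmb at 2.31 ± 0.25 and the growth factor Igf1 at 1.64 ± 0.16 FPKM. All but Igf1 of these 5 were named after their values were seen.

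Of 23 genes of NF-kB signalling and inflammation 21 were detected, at a level of 6.05 ± 0.03. The chemokine genes Ccl3 and Ccl4 were at 1387 ± 70.3 and 701 ± 8.85 FPKM and the NF-kB inhibitor Nfkbia at 539.9 ± 10.2 FPKM, while Il12b was at 0.22 ± 0.22 FPKM. The list shared 3 genes with the dissociation list, Ccl3 and Ccl4 among them. All 20 genes of the type I interferon response were detected, at a lower level of 4.66 ± 0.03, with Ifitm3 at 275 ± 11.5, Bst2 at 114 ± 8.02, Ifi27l2a at 51.3 ± 13.1 and Mx1 at 4.84 ± 0.67 FPKM.

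Antigen presentation genes of class I were all detected (8 of 8, level 6.37 ± 0.05), with H2-D1 at 443 ± 22.1, H2-K1 at 353 ± 13.8 and the regulator Nlrc5 at 2.26 ± 0.12 FPKM. Of 10 class II genes 8 were detected (level 6.18 ± 0.08), with the invariant chain Cd74 at 295 ± 9.51, H2-Aa at 156 ± 13.6, the costimulator Cd86 at 154 ± 4.50 and the regulator Ciita at 0.45 ± 0.10 FPKM. H2-D1, H2-K1 and other class I genes are a multigene family in which reads may be split.

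All 12 TGF-beta pathway genes were detected (level 5.74 ± 0.09), with the receptor genes Tgfbr1 at 603 ± 24.5 and Tgfbr2 at 181 ± 4.66, the repressor Ski at 117 ± 3.82 and the signal transducer Smad2 at 10.9 ± 0.68 FPKM. All 12 genes of the apoptosis list were detected (level 5.36 ± 0.11), with the survival genes Mcl1 at 293 ± 14.2, Bcl2a1b at 194 ± 3.86, Bcl2l1 at 75.0 ± 2.0 and Bcl2 at 3.38 ± 0.67 FPKM. Bcl2a1b belongs to a family of near-identical copies, so its value is uncertain. Proliferation genes had the lowest level of the activation lists, 2.14 ± 0.11 with 16 of 19 detected, and their median was at percentile 80.19 of random lists. The replication factor Pcna was at 100.6 ± 2.20, Mcm3 at 18.7 ± 0.54 and Mcm6 at 12.9 ± 0.84, and the mitotic gene Cenpf at 0.52 ± 0.04 FPKM.

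**Figure D2:**
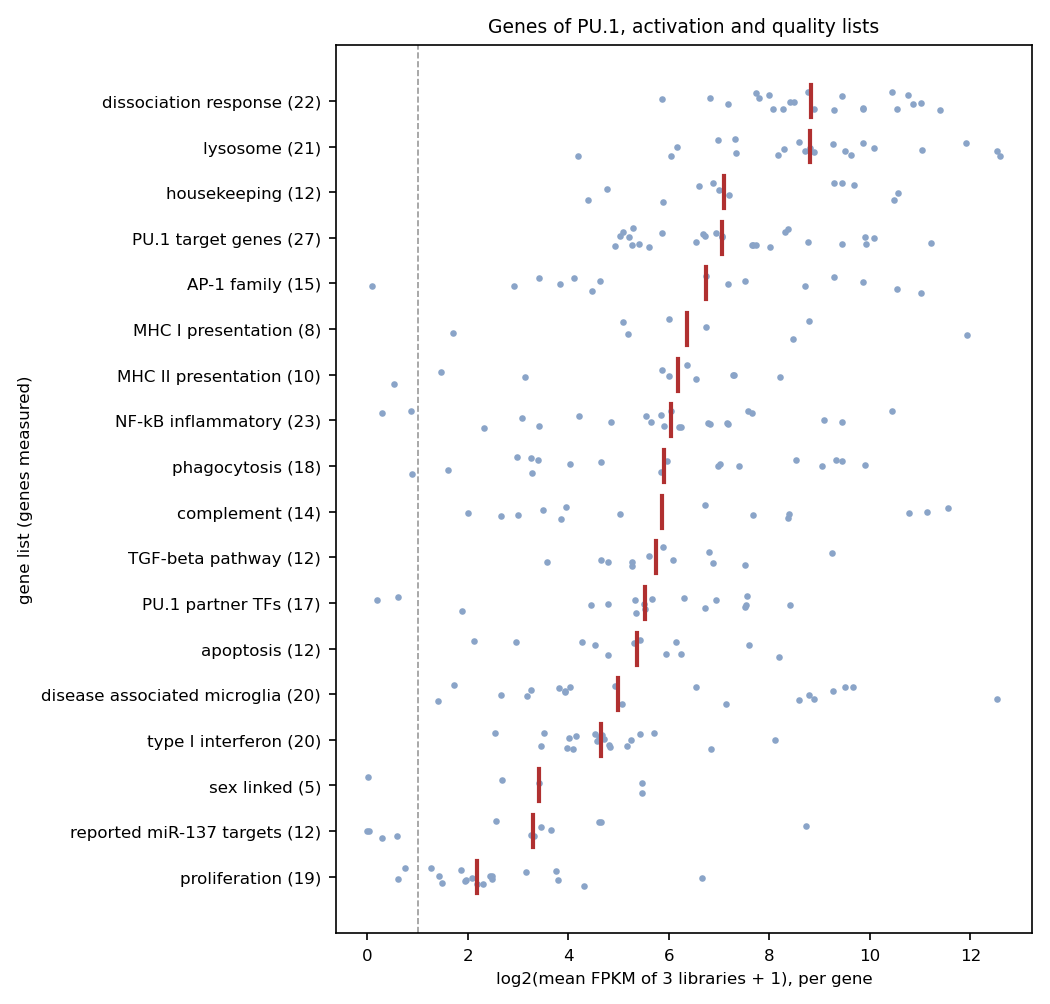
Each point is 1 gene at its mean over the 3 libraries on the axis of log2(FPKM + 1), with the number of genes measured in each list in brackets, the red bar at the list median and the dashed line at an FPKM of 1. The dissociation and lysosomal lists have the highest medians and the proliferation list, with 15 of 19 genes under 10 FPKM, the lowest.

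Genes that tissue dissociation induces had a median level in FPKM near that of lysosomal genes, which depended on the unit and on the median. All 22 were detected, at a level of 8.83 ± 0.06 with 3.26 ± 0.08% of counts, and 21 of them had a mean of at least 100 FPKM. With TMM-normalised CPM in place of FPKM the dissociation and lysosomal levels were 9.71 and 10.28, and with the mean over members 8.99 and 8.85. Besides Fos, the GTPase gene Rhob was at 2678 ± 87.8 and the phosphatase gene Dusp1 at 1848 ± 16.1 FPKM, and the lowest member, the immediate early gene Nr4a1, was at 57.4 ± 2.96 FPKM. All 12 housekeeping genes were detected (level 7.10 ± 0.03), with Actb at 1508 ± 26.0, Ppia at 819 ± 75.8 and Tbp at 19.9 ± 1.90 FPKM. Ribosomal protein genes took 2.11, 2.38 and 2.0% of counts in replicates 1, 2 and 3, a mean of 2.16 ± 0.19% (SD, n = 3), and no mitochondrially encoded gene appeared under its usual symbol. Genes of the Y chromosome were present in every library, with Ddx3y at 43.2 ± 3.35, Eif2s3y at 42.9 ± 1.54 and Uty at 9.66 ± 0.42 FPKM, while Xist of the inactive X chromosome had 0, 7 and 0 counts in replicates 1, 2 and 3. The sex-linked list had 4 of 5 genes detected, a level of 3.41 ± 0.06 and a percentile of 85.68.

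The libraries were then compared with each other. The genes with the highest dispersion between replicates were weakly expressed and included transcripts of other brain cells and of blood. Among genes with a mean of at least 10 CPM the highest dispersion belonged to Atp6v0c, a subunit of the vacuolar proton pump, with 48.7, 11.4 and 17.99 FPKM in replicates 1, 2 and 3 and a biological coefficient of variation of 0.238. It was followed by the fibroblast gene Dcn (5.21, 10.3 and 4.76 FPKM), Gm21975 (4.19, 4.35 and 1.88), the oligodendrocyte genes Omg (6.67, 7.73 and 3.55) and Gjc3 (4.17, 3.07 and 2.06), and Tmem205 (25.0, 14.3 and 27.7 FPKM). Gm7367, Cryba4, Hbb-bs and Gm9855 completed the 10 highest, with coefficients from 0.153 to 0.155. Gm21975, Gm7367 and Gm9855 are predicted genes whose counts could be shared with related sequences. Atp6v0c also had estimated counts that were not whole, 728.39, 155.32 and 256.24, so its values and its spread are uncertain in the same way.

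Across 13246 genes the common biological coefficient of variation, the relative spread beyond counting error, was 0.0827. This value need not be a spread that all genes share. On counts simulated with counting error alone, 200 genes changed 1.5, 2 or 4 times in 1 library gave estimates of 0.033, 0.052 and 0.111. Pearson correlations of log CPM across genes, which are not independent replicates, were 0.992, 0.993 and 0.992 for replicates 1 and 2, 1 and 3, and 2 and 3, with Spearman values of 0.994, 0.994 and 0.993. Each pair differed by more than sampling noise, with a mean chi-square per gene of 5.44, 4.66 and 7.15 in the same order against 1 for counting error alone, so no pair was counted as 1 library. Separate preparations of the same RNA would also exceed that value, and it does not show that the samples were independent. A chi-square test of homogeneity with Benjamini-Hochberg adjustment at 0.05 called 5483 genes as varying between libraries. This is not a count of gene-specific differences: on simulated counts with a coefficient of 0.1 for every gene the same test called 47.6 to 47.8% of unchanged genes. Without replicate 2 the count was 2510 and without replicate 3 it was 3173, which compare 2 libraries in place of 3.

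Gene lists of glia and of border-associated macrophages were highest in replicate 2 and lowest in replicate 3, an order that many other lists shared. Relative to the mean of the 3 libraries, the mean log2 CPM of oligodendrocyte genes was 0.01, 0.17 and -0.18 in replicates 1, 2 and 3. For border-associated macrophage genes it was -0.02, 0.15 and -0.13, and for astrocyte genes -0.01, 0.13 and -0.12. The same order was seen for lymphocyte (-0.03, 0.14 and -0.11), monocyte (-0.04, 0.11 and -0.07) and housekeeping genes (-0.03, 0.07 and -0.04). Homeostatic genes also had it, with smaller deviations (0.0007, 0.02 and -0.02), so it was not particular to glia or border-associated macrophages. Mural and fibroblast genes (-0.11, 0.06 and 0.05) and endothelial genes (-0.05, 0.02 and 0.03) were instead lower in replicate 1 than in the other libraries. Dissociation genes (0.01, -0.05 and 0.03) were lowest and Pu.1 target genes (-0.01, 0.04 and -0.03) highest in replicate 2.

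The spread between libraries was at or above the 95th percentile of 10000 random lists matched on expression for 12 of 30 lists. Chance would give 1.5 for lists of genes that vary independently. Random lists were drawn gene by gene, so genes expressed together can exceed them whenever libraries differ. Lists also shared members, such as 10 of 27 Pu.1 target and 8 of 22 dissociation genes, so the 12 are not separate findings. The percentiles were 100 for oligodendrocyte and border-associated macrophage genes, 99.97 for astrocyte, 99.65 for housekeeping, 99.5 for dissociation, 99.24 for Pu.1 target, 99.2 for disease-associated microglia, 98.4 for monocyte, 97.54 for oligodendrocyte precursor, 97.36 for TGF-beta, 96.25 for mural and fibroblast, and 95.8 for endothelial genes. Homeostatic genes were at percentile 84.39 and neutrophil genes at 93.03. With the median over members in place of the mean 3 lists remained, those of oligodendrocytes, their precursors and astrocytes. Without replicate 2 the count was 7, of which 5 were among the 12. The other 7 of the 12 then ranged from percentile 37.79 for monocyte to 94.21 for oligodendrocyte precursor genes, with Pu.1 target genes at 78.97. Without replicate 1 the endothelial and the mural and fibroblast lists were at percentiles 7.69 and 13.2.

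Short genes were higher in replicate 2. The Spearman correlation across genes between effective length and the log2 difference from the other libraries was 0.07, -0.30 and 0.25 for replicates 1, 2 and 3. With this trend removed, oligodendrocyte, astrocyte and border-associated macrophage genes were at percentile 100 and Pu.1 target genes at 99.02, while TGF-beta (90.5), monocyte (90.74), housekeeping (94.9) and disease-associated microglia genes (94.91) were under the 95th percentile. The lists of NF-kB signalling and inflammation (99.83), AP-1 (97.63) and choroid plexus and ependymal genes (95.91), which were under it before, were then above it.

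**Figure D3:**
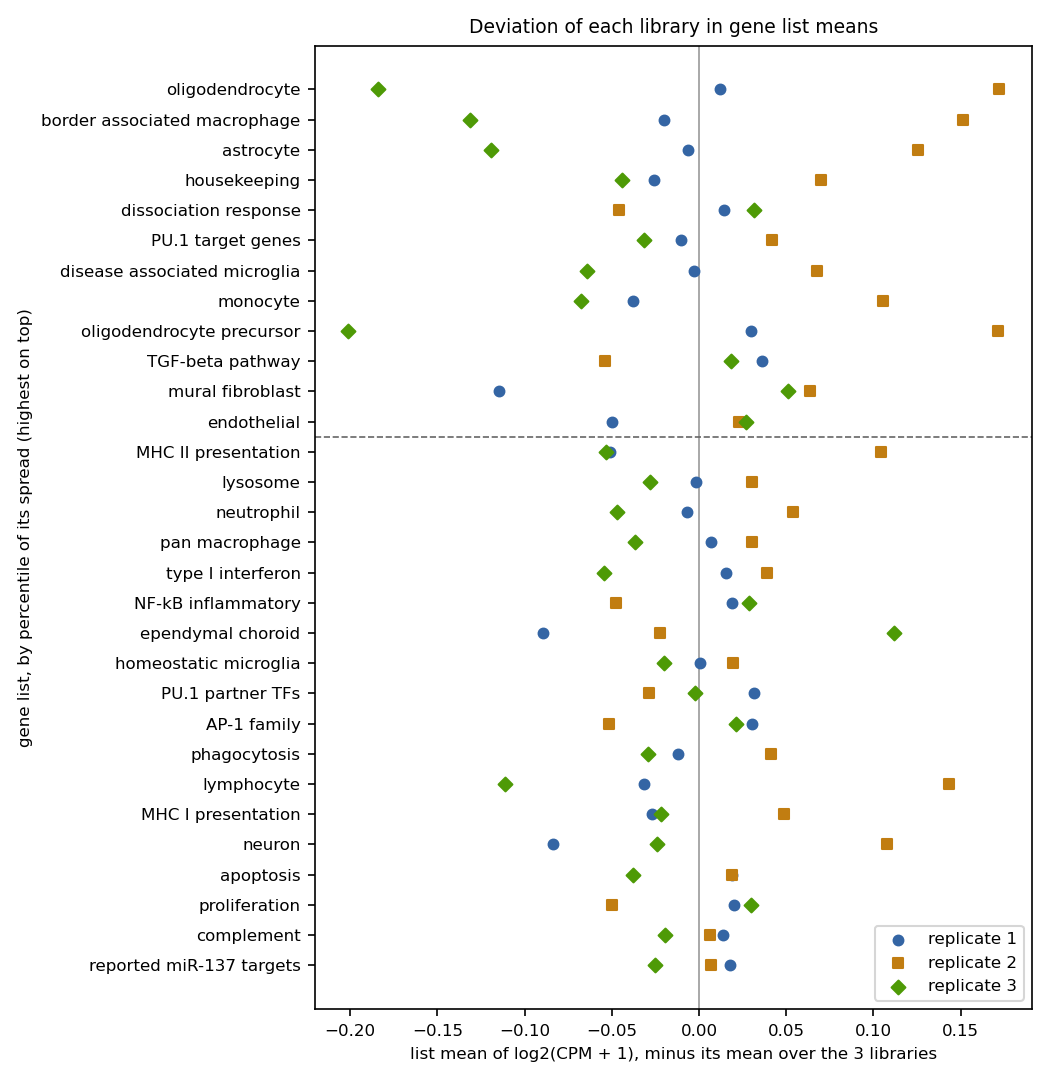
For each of 30 gene lists, the points give the mean over members of log2(CPM + 1) in replicate 1 (circles), 2 (squares) and 3 (diamonds) minus the mean of the 3 libraries, with lists ordered by the percentile of their spread and the dashed line under the 12 lists at or above percentile 95. Oligodendrocyte genes lie at 0.17 in replicate 2 and -0.18 in replicate 3, and homeostatic microglial genes lie in the same order between -0.02 and 0.02.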

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

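The list counts without each replicate and with the trend on effective length removed were chosen after seeing the data, and the other alternatives were fixed beforehand. No paired analysis was possible because there is 1 group. The numbers of detected genes, over all genes and over the homeostatic, other-cell and activation lists, stayed within 1.5 times the reported counts under every alternative run. The homeostatic level stayed above that of each of the 12 other-cell lists and the general macrophage list in every alternative run. With TMM CPM in place of FPKM 9 of the 12 differences from other-cell lists moved by more than 1 SD, to 4.85 for choroid plexus and ependymal and 5.25 for mural and fibroblast genes among others. Over the pooled other-cell genes the difference of 5.51 became 5.19 when members under 0.1 FPKM were left out, a change that follows from removing the lowest members. The common biological coefficient of variation was 0.0827. With DESeq2 the value was 0.102, but this was the square root of the median dispersion over genes and not a common value. How much of the difference comes from the change of summary was not tested. With each replicate left out the common coefficient ranged from 0.0722 (without replicate 2) to 0.0919. The 5483 varying genes became 2510 (without replicate 2) to 3781 when each replicate was left out, where fewer libraries were compared. The 12 varying lists became 3 with the median over members, for which the cause was not tested, and 7 (without replicate 2) to 13 with each replicate left out. The lists of oligodendrocytes, astrocytes and border-associated macrophages stayed above the 95th percentile with each replicate left out (3 lists), and those of oligodendrocytes and astrocytes in every alternative run (2 lists). With the length trend removed 11 lists varied, 8 of them among the 12. Depth limits statements on genes under about 0.2 CPM, and 3 libraries cannot give a sign-flip p under 0.25.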

Other observations

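The 6 gene groups described first were chosen after the tables had been opened but before their values were seen, as were the additional marker lists. The test on effective length was chosen after the neutrophil values were seen. All 10 Toll-like receptors measured were detected, at a level of 4.93 ± 0.06 on the scale of median log2(FPKM + 1) (SD, n = 3), with Tlr7, a sensor of single-stranded RNA, at 356 ± 10.3 FPKM, Tlr13 at 129 ± 1.90 and Tlr8, which also senses single-stranded RNA, lowest at 4.08 FPKM. All 15 chemokine and cytokine receptors were detected (level 6.61 ± 0.04), with Ifngr1 at 573 and Il10ra at 207 FPKM after Cx3cr1, and Il1r1 lowest at 17.6 FPKM. Of 12 purinergic and adenosine genes 9 were detected (level 2.93 ± 0.07). The ectonucleotidase Entpd1, which degrades extracellular ATP, was at 221 FPKM and P2ry6 at 200.4 FPKM, whereas Nt5e, which makes adenosine from AMP, was under 1 FPKM.

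Several iron handling genes were among the abundant transcripts. The ferritin genes Fth1 and Ftl1 were at 3073 and 1719 FPKM and transferrin (Trf) at 1011 FPKM. Of 10 iron genes 9 were detected (level 5.92 ± 0.03), and the hormone gene Hamp was at 0.34 FPKM. All 12 glycolysis genes were detected (level 6.38 ± 0.12), led by Eno1 at 282 FPKM. All 14 genes of lipid and cholesterol handling were detected (level 4.63 ± 0.01), with the lipoprotein receptor Lrp1 at 107 and the exporter Abca1 at 81.2 FPKM, and Nr1h3 lowest at 1.54 FPKM.

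Neutrophil, choroid plexus and endothelial transcripts were present in all 3 libraries although the cells were described as purified microglia. Short effective lengths raise FPKM, with S100a8 over S100a9 at 1.01 ± 0.01 in counts and 2.17 ± 0.03 in FPKM, and how much of the neutrophil level this makes stays open: the 5 neutrophil genes of at least 1000 nt had a median of 65.19 FPKM, but as all 11 neutrophil genes were at 11.7 FPKM or more no subset could have been near 0. Whole-brain RNA carried over would bring neuronal transcripts, and 3 of 10 additional neuronal genes were detected, Nsg2 at 15.7 FPKM being the highest. The fixed neuronal list had also been low, with 3 of 16 genes detected, so this was not an independent test. The low neuronal count argues against carry-over rich in neuronal RNA. It does not cover glial RNA, because 14 of 14 astrocyte and 12 of 12 oligodendrocyte genes were detected. Neutrophils or their RNA, choroid plexus cells or their RNA, and endothelial cells or their RNA in the preparation remain candidate explanations. For each, 10 of 10 additional genes were detected, led by Lcn2 at 424, 1500015O10Rik at 90.0 and Spock2 at 103 FPKM, and no other list holds any of these 10 genes per type. These were not independent tests either, because the fixed lists had already been fully detected (11 of 11, 9 of 9 and 12 of 12 genes). The limit of 1 FPKM was also easily reached, by 11680 of 24411 genes and by all 10 Toll-like receptors. Expression of the neutrophil, choroid plexus and endothelial genes by microglia under this condition stays open. No biological explanation was tested because there is 1 group, and no sort or gate that would remove these cells is described.

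Short genes and ribosomal protein genes were higher in replicate 2 than in the other libraries. The median log2 deviation of the shortest 20% of genes (effective length up to 1379 nt) from the other 2 libraries was -0.02, 0.11 and -0.08 in replicates 1, 2 and 3, and that of the longest 20% (from 4436 nt) 0.02, -0.08 and 0.07. Across 13166 genes outside the ribosomal protein genes the Spearman rho between effective length and the difference of replicate 2 was -0.2906, which describes the trend once more and does not show its cause. RNA integrity and fragment selection were not tested. The ribosomal protein genes had a median of 0.21, at percentile 100 of random lists matched on length and level, whose median was 0.14. The matching used 20 bins of effective length and 5 of level, so differences in length within a bin remained. Random lists of unrelated genes also do not vary together as a gene family can. The test therefore cannot decide whether length accounts for the difference. No biological explanation was tested because the labels give the replicates no difference.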
